A study of Mus musculus with 12 samples.

How the data were processed

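Gene expression was measured in lungs of mice aged 8 to 12 weeks with single-colour Affymetrix mouse arrays, 1 array per sample and 12 arrays in all. The titles of the samples place 3 arrays in each of 4 groups: wild type mice labelled SB, wild type mice given VILI, knockout mice labelled SB and knockout mice given VILI. VILI stands for ventilator-induced lung injury, and per the labels it was produced with a tidal volume of 30 ml/kg at 65 breaths per minute for 4 hours. The labels do not spell out SB, and the series design calls the corresponding wild type group the control. The sample titles write the knockout as GADD45-/- in both treatments. Other labels of the VILI samples write GADD-/-, and the series title names Gadd45a. The series design gives each group 3 mice, so the arrays of a group were taken as separate animals. The description field calls every sample a control animal, VILI samples included, and was not used for grouping. Strain, sex, collection time and hybridisation batch are not given in the sources used here.

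The deposited data held log2 expression values for 45101 probe sets on each array, already normalized by the authors. The submitters' processing notes name MAS5 and GCRMA without saying which of them made the values, in what order or in which version, and detection calls were not part of them. The lowest value of an array lay between 0.67 and 0.69 and the highest between 15.5 and 15.9, and the medians over all probe sets lay between 4.36 and 4.58, so no further transformation, background correction or scaling was applied. Values near the lower end stand for probe sets with little or no signal, and fold changes of genes that lie there in a group are approximate. The number of arrays limits the precision that can be stated.

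The 64 control probe sets were left out. A probe set was kept when at least 3 of the 12 arrays lay above the array's own median, which left 23082 of 45037. Gene names came from the platform annotation, where 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none. Symbols were compared with RefSeq genes of assembly GRCm38.p6 through gene identifiers, 34741 probe sets matched, and 0 symbols changed. Those records served only for names and for which genes neighbour each other, since no genome build is given in the sources used here, and no coordinates are printed. Each gene was represented by its kept probe set with the highest mean over all arrays, which gave 10996 genes, 5056 of them with more than 1 kept probe set. The 3424 kept probe sets without exactly 1 symbol stayed out of the gene-level tests.

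Differential expression was tested with limma 3.58.1 in R 4.3.3, with the data.table package, version 1.17.8, for reading files. A model with 1 mean per group was fitted to all 12 arrays (8 residual degrees of freedom, 3.36 prior degrees of freedom), followed by empirical Bayes moderation with a mean-variance trend. The 7 contrasts were VILI against SB in each genotype, knockout against wild type in each treatment, the interaction (the VILI response of knockout minus that of wild type), and the VILI and genotype effects averaged over the other factor. All tests were two-sided, with Benjamini-Hochberg adjustment over the 10996 genes and a threshold of 0.05. Log2 changes are given with the standard error (SE) of the fitted contrast and group levels as mean ± SD with n = 3.

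Gene lists for lung cell types, inflammation, injury, stress responses and Akt signalling, 28 in all, were fixed with the contrasts and the naming rule before the data were examined. They were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a contrast. Camera with a correlation estimated for each list, and fry, which asks whether the genes of a list move on balance in one direction, were alternatives, and fry's mixed test asks whether they change in either direction. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone. The lists were: acute cytokines and chemokines, NF-kB feedback and adhesion genes, immediate early genes, stretch, injury and coagulation genes, oxidative stress, hypoxia and glycolysis, heat shock and unfolded protein response, interferon response, p53 targets, cell cycle, clock and glucocorticoid response, junction and barrier, PI3K-Akt pathway, Akt-directed ubiquitin ligases and deubiquitinases, Gadd45 family and stress kinase partners, and markers of neutrophils, macrophages and monocytes, T and NK cells, B cells, erythroid cells, endothelium, type II and type I epithelium, club cells, ciliated cells, fibroblasts and smooth muscle, heart and skeletal muscle, and fat. A minimum of 3 measured members was set after the data were seen, which left 27 lists, because the erythroid list had 1 measured member, Bpgm.

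The genes named per contrast were the 10 with the largest rise and the 10 with the largest fall among those past the threshold whose arrays did not overlap between the groups compared (past the threshold alone for the interaction and the averaged contrasts). To these were added the 5 genes of smallest p where nothing passed, up to 4 members of each list past the threshold or else up to 2 given as values, and 16 genes fixed by name, among them the Gadd45 family, Akt1, Akt2, leading cytokines, Nampt, Mylk and sex-linked genes as a check of the animals. Ddx3y had no probe set with 1 symbol and was not analysed here. A gene fixed by name is not reported here. The 3 probe sets of Xist did not pass the brightness limit, and Eif2s3y, on the Y chromosome, had group means of 10.26 to 10.63.

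The test was checked on simulated values for 10996 genes with 100 genes changed at each fold. It recovered 71% of 2-fold and 98% of 4-fold changes for VILI in wild type, 76% and 96% for VILI in knockout, 73% and 95% for knockout against wild type in SB, and 71% and 92% for the same comparison after VILI. For the interaction it recovered 43% of 2-fold and 92% of 4-fold differences. In simulated values for VILI in wild type, camera called 0 of 100 random lists with either correlation, and fry called 1. The simulated noise was independent between genes and arrays, with no array that stood apart. These checks therefore do not cover lists whose genes vary together, or arrays that differ as a whole.

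Alternatives fixed in advance were no brightness limit, a stricter limit at the 70th percentile, no mean-variance trend, quantile normalization, centring on array medians, averaging or separate testing of a gene's probe sets, the replicate number as a block, estimated array weights, fits to the 6 arrays of a comparison, a 2-fold minimum, removal of the 200 measured genes on each side of Gadd45a, and leaving out each array in turn. Pseudocounts were planned for linear values and were not needed. Leaving out the knockout arrays numbered 3 together, and leaving out 3 arrays that stood apart, were added after seeing the data. The labels do not say what a replicate number marks. For knockout against wild type in SB, deviations from the group means of arrays with the same number correlated at 0.231, 0.526 and 0.318, each over the limit of 0.1. For this comparison the numbers were taken as pairing, from the values alone. It was the only pair of groups with all its values over the limit, and no baseline from arrays with different numbers is given for it. The pairing may therefore be chance, and the main fit did not use it. No columns of the table belonged to samples outside the series. No array duplicated another.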

Results

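The data were 12 lung expression arrays from wild type and Gadd45a knockout mice, 3 mice per genotype under SB and 3 after ventilator-induced lung injury (VILI). The design addressed how a lung responds to ventilation at high tidal volume, whether loss of Gadd45a, a small stress-inducible nuclear protein, alters the uninjured or injured lung, and, from the series title, how Akt signalling is involved. Array medians over all probe sets ranged from 4.36 to 4.58 on the log2 scale, and the number of arrays limits the precision. Over 10996 genes, pairs of arrays of the same group correlated at 0.963 to 0.995. The first principal component held 34.3% of the variance and the second 25.2%. Replicate 3 of knockout SB and replicate 3 of knockout VILI stood apart on the second component (scores 42.4 and 27.7), and these arrays had the highest mean B cell marker levels, 9.71 and 10.4, against 5.33 to 7.83 on the others.

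The targeted gene was low in every knockout array. The single probe set of Gadd45a read 8.62, 9.51 and 8.69 in wild type SB (8.94 ± 0.50, SD, n = 3) and 9.75, 9.77 and 10.33 in wild type VILI (9.95 ± 0.33, SD, n = 3). It read 4.87, 6.15 and 4.58 in knockout SB (5.20 ± 0.84, SD, n = 3) and 5.87, 6.02 and 5.36 in knockout VILI (5.75 ± 0.34, SD, n = 3). The knockout difference was -3.74 (SE 0.38, adjusted p = 0.00136) in SB and -4.20 (SE 0.38, adjusted p = 0.00126) after VILI. With only the 6 SB arrays in the fit, the SB call was lost (adjusted p = 0.0627) at the same size of difference. Whether the probes lie inside the deleted part is not known here. VILI left Gadd45a without a significant change in wild type (1.01, adjusted p = 0.167), in knockout (0.55, adjusted p = 0.433) and averaged over genotypes (0.78, adjusted p = 0.0683). Each wild type VILI array lay above each wild type SB array. The average, and the spread used in the tests, include knockout arrays, so they do not describe wild type Gadd45a alone. Of its relatives, Gadd45g rose by 0.79 averaged over genotypes (adjusted p = 0.0157), and Gadd45b was at 0.28 (adjusted p = 0.217); the difference between them was not tested. The other kept probe set of Gadd45b had means of 8.80 in wild type SB, 9.24 in wild type VILI, 8.64 in knockout SB and 9.23 in knockout VILI.

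**Figure D1:**
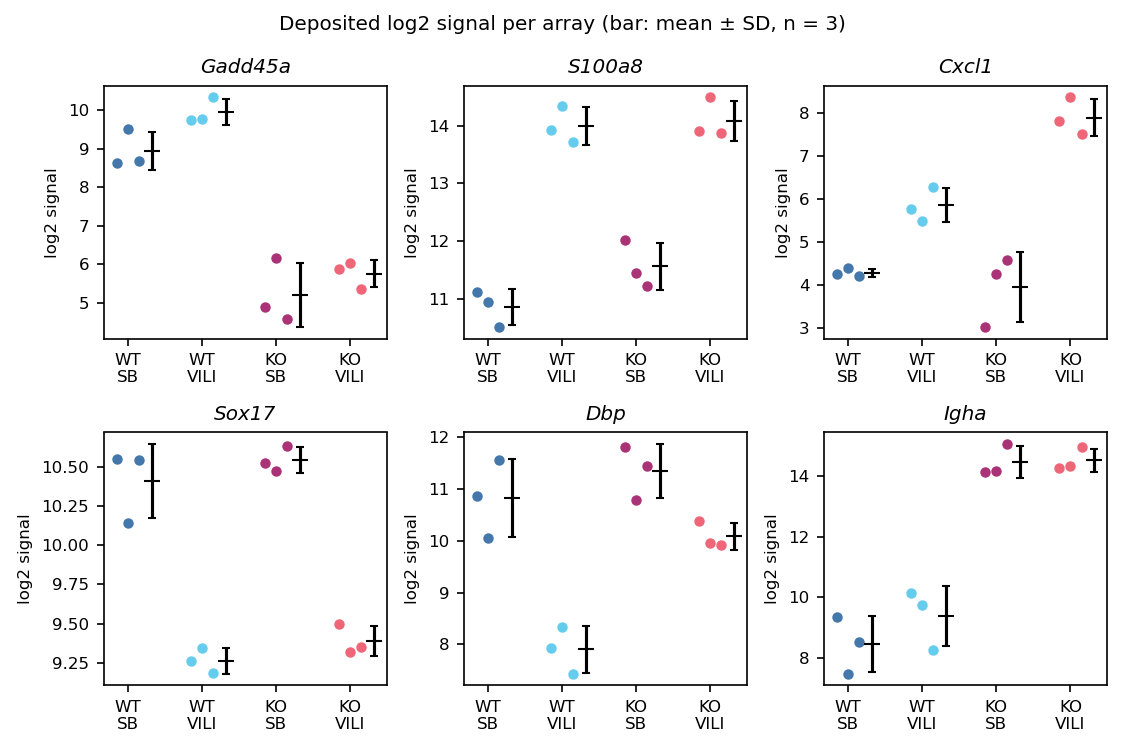
Deposited log2 signal (vertical axis) of Gadd45a, S100a8, Cxcl1, Sox17, Dbp and Igha on each of the 12 arrays, by genotype (WT, wild type; KO, knockout) and treatment. Points are arrays and the bar beside them is the mean ± SD (n = 3); Gadd45a lay at 8.62 or above on every wild type array and at 6.15 or below on every knockout array.

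The first comparison asked what VILI changed in wild type lungs. Transcripts of neutrophils rose most. Mmp8, the neutrophil collagenase, rose by 4.91 on the log2 scale (SE 0.73, adjusted p = 0.0114), the lectin receptors Clec4e and Clec4d by 4.73 (SE 0.67, adjusted p = 0.00768) and 3.39 (SE 0.38, adjusted p = 0.00209), and the decoy interleukin-1 receptor Il1r2 by 4.04 (SE 0.67, adjusted p = 0.0179). S100a8 and S100a9, which form the abundant neutrophil protein calprotectin, rose by 3.13 (SE 0.25) and 3.38 (SE 0.29), 10.4-fold for S100a9, both with adjusted p = 0.000416. S100a9 went from 9.88 ± 0.34 to 13.26 ± 0.39 (SD, n = 3). Csf3r, the receptor of granulocyte colony-stimulating factor, rose by 2.88 (adjusted p = 0.00675), Stfa2l1, a neutrophil cystatin, by 3.17, and the Schlafen genes Slfn4 and Slfn1 by 3.92 and 3.43. Of 15 measured neutrophil markers, 9 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 2.61 (camera adjusted p = 8.92e-16, and 0.138 with an estimated correlation).

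Inflammatory mediators and early transcription factors rose with them in wild type. Of 9 measured acute cytokines and chemokines, 4 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 2.0 (adjusted p = 1.16e-07, and 0.0451 with an estimated correlation). The called genes were the neutrophil chemoattractants Cxcl2 (2.87, adjusted p = 0.0260), Cxcl5 (2.85, adjusted p = 0.0490) and Cxcl1 (1.57, adjusted p = 0.0492), and Il1b (2.69, adjusted p = 0.0183). Il6 (2.43, SE 0.79, adjusted p = 0.113), Ptgs2, the inducible cyclooxygenase (1.84, adjusted p = 0.186), and Nampt (0.37, adjusted p = 0.201) did not pass. Among 25 immediate early genes, Egr2 (2.61), Myc (2.56) and Jun (0.74) rose (7 rose and 0 fell adjusted over the list alone; median 0.45, adjusted p = 1.49e-06, and 0.399 with an estimated correlation). Of 15 stretch, injury and coagulation genes, 3 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.70, adjusted p = 3.67e-06, and 0.154 with an estimated correlation). Tissue factor F3 (1.29) and the epithelial keratins Krt8 (1.13) and Krt18 (1.09) rose, and endothelin 1, Edn1, fell by 1.57. The metallothioneins Mt2 (2.13) and Mt1 (1.70) and the cystine transporter gene Slc7a11 (2.21) were the 3 of 19 oxidative stress response genes that rose (6 and 0 adjusted over the list alone; median 0.06, adjusted p = 0.00277, and 0.399 with an estimated correlation). Adm, the vasodilator adrenomedullin, rose by 2.14 and was the only called gene of 15 in the hypoxia and glycolysis list (1 rose and 1 fell adjusted over the list alone; median 0.17, adjusted p = 0.0121, and 0.281 with an estimated correlation). Dio2, which activates thyroid hormone, rose by 3.16, Krtap17-1 by 3.61, and Sesn1 by 0.70, the only called gene among 17 p53 targets (adjusted p = 0.122 for the list).

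Endothelial, ciliated, type I epithelial and club cell lists were shifted downward in wild type after VILI, and those of type II epithelium and of fibroblasts and smooth muscle did not pass. Smad6, an inhibitor of bone morphogenetic protein signalling, fell by 1.67 (SE 0.14, adjusted p = 0.000416), Sox17, an endothelial transcription factor, by 1.15 (SE 0.12, adjusted p = 0.00151), and Gja4, an arterial connexin, by 1.41 (adjusted p = 0.0235). Of 24 endothelial markers, 0 rose and 1 fell (0 and 4 adjusted over the list alone; median -0.34, adjusted p = 0.000777, and 0.399 with an estimated correlation). Of 13 ciliated cell markers, 3 fell (9 adjusted over the list alone; median -0.57, adjusted p = 1.63e-06, and 0.399 with an estimated correlation): Foxj1, the master regulator of motile cilia, at -1.70, Tekt4 at -1.64 and Dynlrb2 at -0.57. Rtkn2 (-1.07) fell among 12 type I epithelial markers (adjusted p = 0.0284, and 0.543 with an estimated correlation), and club cell markers had a median of -0.20 with 0 calls (0 rose and 3 fell adjusted over the list alone; adjusted p = 0.0353, and 0.543 with an estimated correlation). Tagln, a smooth muscle gene, fell by 0.49. Genes of the circadian clock fell: Dbp at -2.91 (SE 0.37, adjusted p = 0.00427), Per3 at -2.30, Ciart at -1.86 and Nr1d2 at -0.67. The clock and glucocorticoid list as a whole, 2 higher and 5 lower adjusted over the list alone, was not shifted (adjusted p = 0.525). Mycl (-2.54), Hykk (-1.70), Tbc1d30 (-1.69) and 2810410L24Rik (-1.93) completed the largest falls.

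In all, limma called 290 genes for VILI in wild type, 149 higher and 141 lower. Of the 27 lists, 13 were shifted, 9 up and 4 down, and acute cytokines and chemokines were the only list that held with an estimated correlation. T and NK cell markers (median 0.58, adjusted p = 0.00244, 0 calls), NF-kB feedback and adhesion genes (0.21, adjusted p = 0.00593; 4 higher adjusted over the list alone, Bcl3 at 1.63 and Nfkbiz at 1.13 with adjusted p = 0.0517) and macrophage and monocyte markers (0.28, adjusted p = 0.0194, 0 calls) were shifted upward, at 0.412, 0.399 and 0.543 with an estimated correlation. The remaining lists gave adjusted p of 0.101 for heat shock, 0.135 for the Gadd45 family and stress kinases, 0.215 for B cells, 0.324 for fibroblasts and smooth muscle, and 0.343 for cell cycle. Type II epithelium had 0.443, heart and skeletal muscle 0.669, fat 0.828, and junction and barrier genes 0.917. For muscle, junctions and the PI3K-Akt pathway the sign of the median, mean or test differed. Bpgm, the measured erythroid gene, was at -0.18 (adjusted p = 0.439). Centring the arrays gave 190 higher and 103 lower, a share of 64.8% higher against 51.4%. Single arrays moved the count. It was 19, 59 and 74 genes without wild type VILI replicates 2, 1 and 3. It was 31 and 135 without wild type SB replicates 3 and 2, and 182 and 487 without knockout SB replicates 1 and 3. Of 44 named genes past the threshold, 11 stayed past it in each of the 12 fits without 1 array (Ciart, Clec4d, Csf3r, Dbp, Hykk, S100a8, S100a9, Slfn4, Smad6, Sox17 and Stfa2l1), and the others reached adjusted p between 0.0578 (Clec4e) and 0.172 (Tbc1d30) without the array that mattered most to each. Among the list calls, those of T and NK cells (0.0615 without wild type SB replicate 2), NF-kB genes (0.0537 without wild type SB replicate 1), macrophages (0.130 without wild type VILI replicate 1), type I epithelium (0.115 without wild type SB replicate 2) and club cells (0.187 without wild type SB replicate 3) were lost. The lowest group means of Mmp8, Clec4e, Slfn1, Dio2, Cxcl1, Cxcl2, Cxcl5, Slc7a11, Mycl, Tbc1d30 and Tekt4 lay below the array medians, so their folds are approximate.

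In knockout lungs, VILI also raised cytokine and neutrophil transcripts. Il6 rose by 4.86 (SE 0.79, adjusted p = 0.0108), Cxcl5 by 4.55 (SE 0.67, adjusted p = 0.00788), Cxcl2 by 3.98 (SE 0.55, adjusted p = 0.00596), Cxcl1 by 3.94 (SE 0.37, adjusted p = 0.00155), Ptgs2 by 3.27 (SE 0.74, adjusted p = 0.0322) and Il1b by 2.63 (adjusted p = 0.0131). Cxcl1 went from 3.94 ± 0.82 to 7.89 ± 0.43 (SD, n = 3). Of 9 measured acute cytokines and chemokines, 6 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 3.27 (adjusted p = 1.25e-08, and 0.0309 with an estimated correlation). Among neutrophil markers, Mmp8 rose by 4.90 (SE 0.73, adjusted p = 0.00845), Clec4e by 4.17, Il1r2 by 3.93, Clec4d by 3.31, S100a9 by 2.82 (SE 0.29, adjusted p = 0.00158) and S100a8 by 2.52 (SE 0.25, adjusted p = 0.00158). Of 15, 9 rose and 0 fell (14 and 0 adjusted over the list alone; adjusted p = 1.17e-12, and 0.170 with an estimated correlation). Nampt (0.59) had an adjusted p of 0.0572.

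Stress and injury genes rose in knockout lungs as well. Of 19 oxidative stress response genes, 9 rose and 0 fell (11 and 2 adjusted over the list alone; median 0.98, adjusted p = 8.54e-06, and 0.213 with an estimated correlation), among them Slc7a11 (3.44), Mt2 (2.43), Mt1 (2.08) and Gclc (1.30), which encodes the catalytic subunit of the first enzyme of glutathione synthesis. Of 15 stretch, injury and coagulation genes, 5 rose and 0 fell (11 and 1 adjusted over the list alone; median 1.18, adjusted p = 7.76e-06, and 0.170 with an estimated correlation), including Krt8 (1.63), Tnc, the matrix protein tenascin C (1.61), the growth factor Hbegf (1.52) and Krt18 (1.38). Fosl1 (3.40), Egr1 (2.81), Myc (2.36) and Egr2 (2.08) were among 5 of 25 immediate early genes that rose (9 and 0 adjusted over the list alone; adjusted p = 1.31e-05, and 0.513 with an estimated correlation). The signalling inhibitors and regulators Socs3 (2.36), Bcl3 (2.24), Tnfaip2 (1.41) and Birc3 (0.91) were among 5 of 17 NF-kB feedback and adhesion genes that rose (7 and 1 adjusted over the list alone; adjusted p = 0.000221, and 0.213 with an estimated correlation). Cldn4, a tight junction claudin, rose by 4.12 (SE 0.92, adjusted p = 0.0306) and Sfn, the epithelial 14-3-3 sigma protein, by 3.43 (SE 0.45, adjusted p = 0.00586). Cxcl10 (3.12) and Ifit1 (1.24) were the 2 of 17 interferon response genes that rose (3 and 0 adjusted over the list alone; median 0.26, adjusted p = 0.0321, and 0.647 with an estimated correlation). The glucose transporter gene Slc2a1 (1.41) was the only hypoxia and glycolysis gene called (6 and 2 adjusted over the list alone; adjusted p = 0.0131, and 0.213 with an estimated correlation). Plk2 (1.30), a p53 target, Asns (0.80), asparagine synthetase, and Map2k4 (0.48), a stress kinase, rose too.

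Endothelial transcripts fell in knockout lungs. Of 24 markers, 0 rose and 6 fell (0 and 11 adjusted over the list alone; median -0.42, adjusted p = 1.65e-07, and 0.213 with an estimated correlation), among them Sox17 by 1.16 (SE 0.12, adjusted p = 0.00158), the angiopoietin receptor Tek by 0.97, endoglin, Eng, by 0.94 and Calcrl by 0.82. Gja4 fell by 1.75 (SE 0.26, adjusted p = 0.00788), the aminopeptidase Anpep by 2.20, the endothelial heat shock family member Hspa12b by 1.99, 2810410L24Rik by 1.92, Akap14 by 1.89, Kank4 by 1.80, N4bp3 by 1.69, Wscd1 by 1.66, Cckar by 1.59 and Nrn1 by 1.56. Rtkn2 fell by 1.14 in the type I epithelial list (adjusted p = 0.0370, and 0.576 with an estimated correlation), and Cyp2f2, a club cell cytochrome P450, by 0.37 (0 higher and 5 lower club cell markers adjusted over the list alone; adjusted p = 0.0117, and 0.530 with an estimated correlation). Type II epithelial (median -0.24, adjusted p = 0.00316, 2 lower adjusted over the list alone) and ciliated cell markers (median -0.29, adjusted p = 0.0117) were shifted with 0 calls, at 0.548 and 0.576 with an estimated correlation. Of the clock genes named in wild type, Ciart fell by 1.29 (adjusted p = 0.0108) in knockout and stayed past the threshold in each fit without 1 array (highest adjusted p = 0.0482); it was added after its values were seen. Dbp was at -1.26 (adjusted p = 0.0770), Per3 at -1.12 (adjusted p = 0.192) and Nr1d2 at -0.20 (adjusted p = 0.370).

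Over all genes, 491 passed for VILI in knockout, 304 higher and 187 lower (61.9% higher, against 267 and 239, or 52.8%, with centred arrays). In this comparison 13 lists were shifted, 8 up and 5 down, of which acute cytokines and chemokines held with an estimated correlation. The count was 69 and 192 without knockout VILI replicates 2 and 3, 182 and 306 without knockout SB replicates 1 and 2, and 311 without wild type VILI replicate 2. With only the 6 knockout arrays it was 11. Of 53 named genes past the threshold, 24 stayed past it in each of the 12 fits, and the others, Il6 included (0.0556 without knockout VILI replicate 2), reached adjusted p between 0.0518 (Nrn1) and 0.177 (Asns). The list calls for ciliated cells (0.0741) and hypoxia (0.0504) were lost without knockout VILI replicate 2, and those for club cells (0.0661), type II (0.112) and type I epithelium (0.366) and interferon response (0.324) without knockout VILI replicate 3. Quantile normalization also ended the type I and club cell calls. Mmp8, Il6, Cxcl1, Cxcl2, Cxcl5, Clec4e, Cldn4, Slc7a11, Fosl1 and Akap14 had a group mean below the array medians, so their folds are approximate.

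The next question was whether the response to VILI depended on the genotype. It was largely shared: log2 changes of the genotypes, which have no array in common, correlated across genes at r = 0.766 (Spearman's rho = 0.690) over 10996 genes and at 0.909 over the 617 genes called in either, 607 of which had the same sign. Genes are not independent replicates, so these values are descriptive. The genotypes shared 107 risen genes (4.12 expected from independent lists) and 57 fallen genes (2.40 expected), and 0 genes passed in opposite directions. Each gene's spread came from the same fit in both genotypes, so the lists are not independent and those expected counts are rough guides. For the interaction itself, limma called 0 genes, with 288 at an unadjusted p under 0.05 against 550 expected, and 0 genes under each alternative that was run. The 5 genes of smallest p, given as values, were Lrmda (1.89, SE 0.37), Eml2 (1.02, SE 0.21), Ap2b1 (1.24, SE 0.27), Cxcl1 (2.38, SE 0.52) and Lrig1 (0.92, SE 0.21), all with adjusted p = 0.9999. Il6 had an interaction of 2.43 (SE 1.11), Dbp of 1.65 (SE 0.52), Gadd45g of -0.19 (SE 0.37) and Akt1 of 0.15 (SE 0.22).

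**Figure D2:**
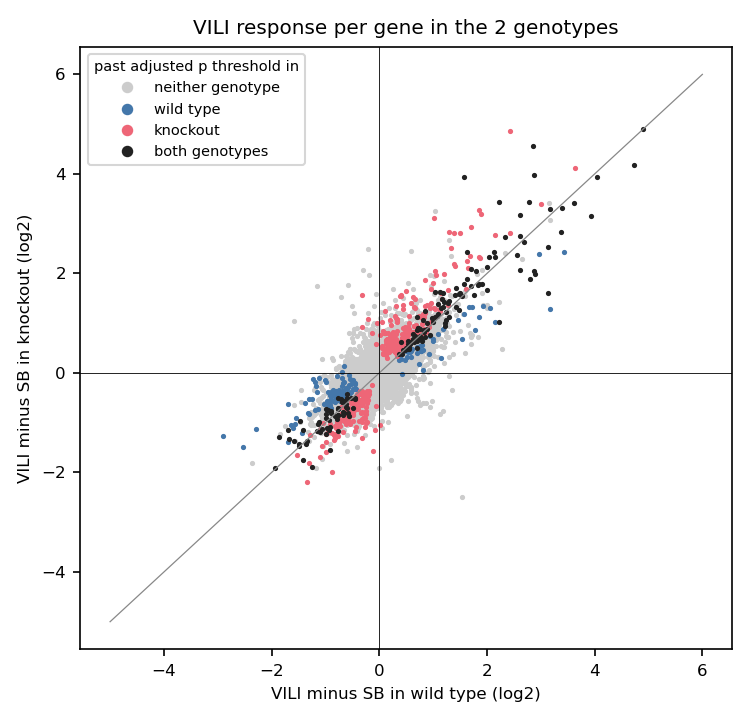
Log2 change with VILI of each of 10996 genes in wild type (horizontal axis) and in knockout (vertical axis), 3 arrays per group. Colours mark genes past the threshold in neither genotype, in wild type, in knockout or in both; the line marks equal change, and the correlation across genes was 0.766.

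Lists gave a different picture from single genes for the interaction. Acute cytokines and chemokines had a median of 1.10 (adjusted p = 0.0317), interferon response genes of 0.48 (adjusted p = 0.00317), ciliated cell markers of 0.39 (adjusted p = 0.00472) and oxidative stress response genes of 0.38 (adjusted p = 0.00492), with the more positive change in knockout. T and NK cell markers (-0.37, adjusted p = 0.00142), macrophage and monocyte markers (-0.23, adjusted p = 0.00317), endothelial markers (-0.11, adjusted p = 0.00575) and type II epithelial markers (-0.09, adjusted p = 0.00566) had the more negative change in knockout. None of the 8 held with an estimated correlation (adjusted p = 0.748 for each), and 59 of 100 drawn splits of the arrays, the real one included, shifted at least 8 lists. Each was also lost without single arrays. Cytokines were at 0.330, oxidative stress at 0.231 and T and NK cells at 0.0711 without knockout VILI replicate 2. Type II epithelium was at 0.464, endothelium at 0.383 and interferon response at 0.261 without knockout VILI replicate 3. Macrophages were at 0.200 and ciliated cells at 0.160 without knockout VILI replicate 1. Without knockout SB replicate 3 the number of shifted lists was 3.

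Knockout against wild type was then compared in the SB lungs. Immunoglobulin transcripts were far higher in knockout: Igha, the immunoglobulin A heavy chain, by 5.97 (SE 0.52, adjusted p = 0.000286) and the kappa variable gene Igkv6-14 by 5.60 (SE 0.58, adjusted p = 0.00136). Pik3ap1, an adaptor that links B cell receptor signals to phosphoinositide 3-kinase, was higher by 4.17 (SE 0.52, adjusted p = 0.00576), the matrix protein gene Fbln2 by 2.15 (SE 0.18, adjusted p = 0.000286) and Nnt, the mitochondrial transhydrogenase, by 1.52 (SE 0.13, adjusted p = 0.000286). Besides Gadd45a, 6 genes were lower: Mid1 at -3.36 (SE 0.39, adjusted p = 0.00332), Lrmda at -3.04 (SE 0.26, adjusted p = 0.000286), Erdr1 at -2.20 (SE 0.32, adjusted p = 0.0256), Hps1 at -1.89 (SE 0.15, adjusted p = 0.000286), Tnc at -1.88 (SE 0.28, adjusted p = 0.0292) and the matrix gene Smoc2 at -1.07 (SE 0.12, adjusted p = 0.00300). These 12 genes, 5 higher and 7 lower, were all that passed. Other probe sets of Igha (5.88 and 6.99) and Nnt (1.56) gave like values, while those of Hps1 (-0.14), Tnc (-0.46) and Smoc2 (-0.23) gave smaller ones. Leaving out wild type SB replicate 3 ended the calls of Pik3ap1 (adjusted p = 0.0507), Erdr1 (0.112) and Tnc (0.153), and the other 9 stayed in each of the 12 fits. With the replicate number as a block, Tnc did not pass (adjusted p = 0.0800), and Vwf (-0.67, adjusted p = 0.00821) and Mindy4 (1.68, adjusted p = 0.0277), named only because the block changed their calls, passed. Folds of Igkv6-14, Mid1 and Lrmda are approximate because of low signal in a group.

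Lymphocyte marker lists were shifted upward and the fibroblast and smooth muscle list downward in knockout SB lungs by camera, with 0 of their genes called over all genes and none of the lists past the threshold by fry. T and NK cell markers had a median of 0.88 (adjusted p = 1.91e-07, and 0.448 with an estimated correlation; fry adjusted p = 0.215), with 0 calls adjusted over the list alone. B cell markers had a median of 1.10 (adjusted p = 1.58e-05, and 0.456 with an estimated correlation; fry adjusted p = 0.510), with 1 higher adjusted over the list alone. Jchain, the joining chain of secreted antibodies, differed by 5.39 (SE 1.05, adjusted p = 0.132) without passing. Without knockout SB replicate 3, the array with the highest B cell markers in its group, the B cell list was at adjusted p = 0.110, cell cycle genes (median 0.36, adjusted p = 0.00677, and 0.781 with an estimated correlation) at 0.407, heat shock genes (0.24, adjusted p = 0.000588, and 0.456 with an estimated correlation) at 0.104 and oxidative stress genes (-0.41, adjusted p = 0.00913, and 0.521 with an estimated correlation; 3 lower adjusted over the list alone) at 0.138. Fibroblast and smooth muscle markers had a median of -0.49 (adjusted p = 0.000588, and 0.456 with an estimated correlation; fry adjusted p = 0.135), with 0 calls over all genes and 7 lower adjusted over the list alone. Stretch, injury and coagulation genes (-0.38, adjusted p = 0.00283), ciliated cell markers (-0.46, adjusted p = 5.11e-05) and, upward, neutrophil markers (0.39, adjusted p = 0.000423) were shifted, each at 0.456 with an estimated correlation. The fibroblast, stretch and ciliated calls held in each fit without 1 array. Over all alternatives run with camera at the preset correlation they reached adjusted p of 0.0585, 0.233 and 0.0677, and neutrophil markers 0.01175. Type I epithelial markers (-0.27, adjusted p = 0.0273; 3 lower adjusted over the list alone), clock and glucocorticoid response genes (0.17, adjusted p = 0.0157) and macrophage markers (0.11, adjusted p = 0.0273) completed the 12 shifted lists, and had 0.702, 0.448 and 0.702 with an estimated correlation. Those 3 were lost without single arrays (0.122 without wild type SB replicate 2, 0.121 without knockout SB replicate 3 and 0.101 without knockout SB replicate 2), and quantile normalization ended the last pair.

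After VILI, most of the same genotype differences stood. Igkv6-14 was higher in knockout by 6.42 (SE 0.58, adjusted p = 0.00126), Igha by 5.11 (SE 0.52, adjusted p = 0.00151), Pik3ap1 by 4.56 (SE 0.52, adjusted p = 0.00336), Fbln2 by 1.79 (SE 0.18, adjusted p = 0.00151) and Nnt by 1.34 (SE 0.13, adjusted p = 0.00151). Besides Gadd45a, Mid1 (-2.62, adjusted p = 0.0326), elastin, Eln (-1.71, SE 0.20, adjusted p = 0.00488), Igf1, insulin-like growth factor 1 (-1.54, SE 0.21, adjusted p = 0.0189), Hps1 (-1.38, adjusted p = 0.00201) and Smoc2 (-0.80, adjusted p = 0.0326) were lower. The other probe set of Hps1 was at -0.03, while those of Igha, Nnt, Eln, Igf1 and Smoc2 differed in the same direction as the probe sets used. Of the 11 genes, 5 higher and 6 lower, 9 had passed in SB in the same direction, against 0 expected from independent lists. The shared spread per gene makes that expected count a rough guide here too. Cxcl1 (2.04, adjusted p = 0.0817), Dbp (2.17, adjusted p = 0.0662), Il6 (1.97, adjusted p = 0.691), Cxcl2 (1.67, adjusted p = 0.538), Cxcl5 (2.49, adjusted p = 0.347) and Jchain (5.66, adjusted p = 0.103) did not pass. The calls of Igf1 (0.110 without wild type VILI replicate 1), Mid1 (0.171 without wild type VILI replicate 3) and Smoc2 (0.217 without wild type VILI replicate 2) were lost in fits without 1 array. The count was 17 without wild type SB replicate 1 and 42 without knockout VILI replicate 1.

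Of the 27 lists, 14 were shifted for genotype after VILI. Acute cytokines and chemokines had a median of 1.0 (adjusted p = 1.06e-05, and 0.120 with an estimated correlation), with 0 calls over all genes and 3 higher adjusted over the list alone. Interferon response genes were at 0.42 (adjusted p = 1.06e-05, and 0.523 with an estimated correlation) and fibroblast and smooth muscle markers at -0.40 (adjusted p = 1.06e-05, and 0.332 with an estimated correlation), with Eln called and 7 lower adjusted over the list alone. B cell (1.17) and cell cycle (0.67) lists, each at adjusted p = 0.000150 and at 0.610 with an estimated correlation, were at 0.351 and 0.350 without knockout VILI replicate 3, the array with the highest B cell markers, and the cell cycle list then turned downward. Without it, NF-kB genes (0.34, adjusted p = 0.00150, and 0.523 with an estimated correlation) were at 0.0531, endothelium (-0.10, adjusted p = 0.0324) at 0.793, and type I (-0.16, adjusted p = 0.0201) and type II epithelium (-0.14, adjusted p = 0.00420) and junctions (-0.12, adjusted p = 0.0362) at 0.465. The last 4 had 0.610 with an estimated correlation. Heat shock genes (0.32, adjusted p = 0.000474, and 0.523 with an estimated correlation) were at 0.0858 without knockout VILI replicate 2. Clock and glucocorticoid genes (0.21, adjusted p = 0.0324, and 0.332 with an estimated correlation; 6 higher and 3 lower adjusted over the list alone) and stretch genes (-0.11, adjusted p = 0.0361, and 0.610 with an estimated correlation) were at 0.130 and 0.253 without knockout VILI replicate 1, and neutrophil markers (0.16, adjusted p = 0.0417, and 0.659 with an estimated correlation) at 0.582 without wild type VILI replicate 3 and, turned downward, at 0.436 without knockout VILI replicate 2. Quantile normalization ended the calls of type I epithelium, endothelium, stretch, junctions and neutrophils.

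**Figure D3:**
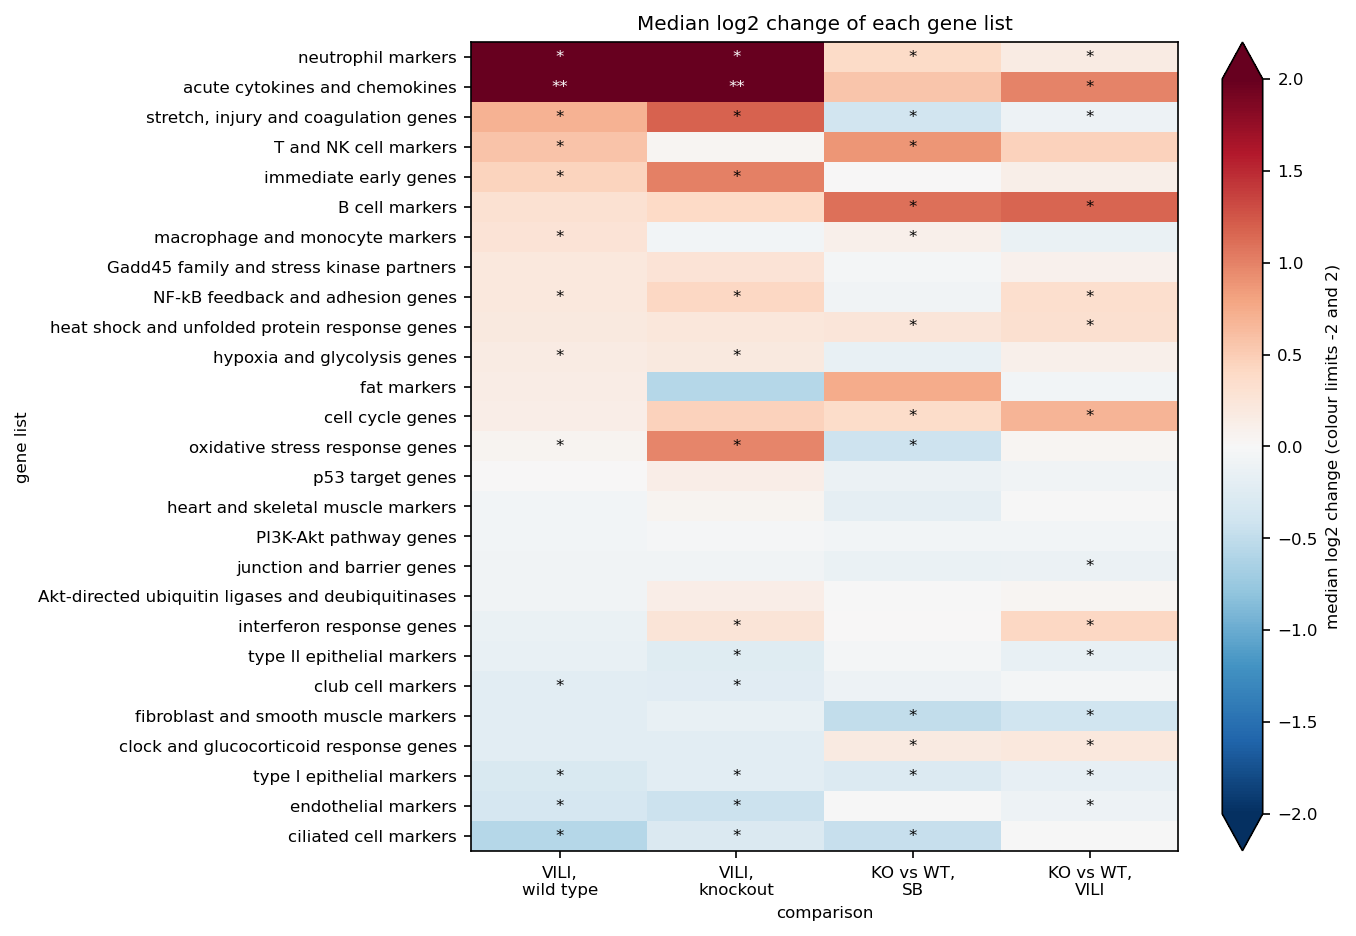
Median log2 change (colour, limits -2 and 2) of 27 gene lists in 4 comparisons: VILI in each genotype, and knockout (KO) against wild type (WT) in each treatment. An asterisk marks camera's adjusted p under 0.05 and a double asterisk marks lists that held with an estimated correlation, which were the acute cytokines and chemokines with VILI in either genotype.

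With the genotypes averaged, which compares 6 arrays with 6, VILI changed 1958 genes, 926 higher and 1032 lower, 189 and 81 of them by at least 2-fold. Genes that missed the threshold in a single genotype passed here. Il6 rose by 3.64 (SE 0.56, adjusted p = 0.00235), Ptgs2 by 2.56 (SE 0.52, adjusted p = 0.00890) and Nampt by 0.48 (SE 0.11, adjusted p = 0.0145), while Mylk, the myosin light chain kinase, fell by 0.32 (SE 0.08, adjusted p = 0.0176). Endothelial markers fell in 11 of 24 (14 adjusted over the list alone), with Eng at -0.77, Calcrl at -0.65 and Egfl7 at -0.42. Surfactant protein C, Sftpc (-0.20), the club cell secretoglobin Scgb1a1 (-0.20), the lung lineage factor Nkx2-1 (-0.78), the junction gene Jup (-0.91), the fibroblast factor Tcf21 (-0.99) and Vegfa (-0.33) fell, and Cldn4 (3.88), Cd14 (0.83), Hif1a (0.41), Atf4 (0.78) and Rsad2 (1.36) rose. Of 27 lists, 12 were shifted, and acute cytokines and chemokines (median 2.66, adjusted p = 2.43e-08) held with an estimated correlation (adjusted p = 0.0345). Of 93 named genes past the threshold, 81 stayed past it in each of the 12 fits. The count was 1128 without wild type VILI replicate 2, 1206 without knockout VILI replicate 2, 1227 without wild type SB replicate 3 and 1291 without wild type VILI replicate 1.

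The list of Akt pathway transcripts, the theme of the series title, was not shifted as a whole in any comparison, and its members went both ways. Akt1 was at -0.23 (adjusted p = 0.439) with VILI in wild type, -0.08 (adjusted p = 0.810) with VILI in knockout, -0.20 (adjusted p = 0.686) in knockout SB against wild type and -0.06 (adjusted p = 0.952) after VILI. Akt2 was at -0.16, 0.02, -0.35 and -0.17 in the same comparisons (adjusted p = 0.586, 0.946, 0.455 and 0.820). The other kept probe sets of Akt2 went the other way with VILI in wild type, from 7.30 to 7.74 and from 4.57 to 4.90, and in knockout read 7.36 and 7.43, and 4.41 and 4.66, in SB and VILI. Of 26 measured PI3K-Akt pathway genes, 0 passed for VILI in either genotype (adjusted p of the list = 0.918 in wild type and 0.444 in knockout). The mixed test of fry, for change in either direction without comparison with other genes, gave this list adjusted p of 0.00249 in wild type, 0.00454 in knockout and 1.31e-06 with genotypes averaged. With genotypes averaged, 1 rose and 3 fell, the same as adjusted over the list alone: Pik3ca, a catalytic subunit of phosphoinositide 3-kinase, rose by 0.40 (adjusted p = 0.0138), and the phosphatase genes Inppl1 and Phlpp1 and the regulatory subunit gene Pik3r2 fell by 0.66, 0.47 and 0.73. Of 9 ubiquitin ligases and deubiquitinases that act on Akt, Nedd4 fell by 0.53 (adjusted p = 0.0191) with VILI in knockout, was at -0.42 (adjusted p = 0.0523) in wild type, and fell together with Ttc3 (-0.48 and -0.45) in the averaged contrast (2 adjusted over the list alone); the sign of this list's median, mean or test differed there. The knockout effect on the pathway list had adjusted p of 0.510 in SB and 0.598 after VILI, and on the ligase list of 0.682 and 0.390. The arrays measured transcripts, and protein amount or phosphorylation of Akt was not part of these data.

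Averaged over treatments, 50 genes differed by genotype, 12 higher and 38 lower in knockout. Immunoglobulin genes filled the top: Igkv6-14 (6.01, adjusted p = 1.94e-05), Igkv9-120 (5.91), Igk (5.87), Igha (5.54, adjusted p = 1.94e-05), Igkv8-30 (4.70) and Igkv15-103 (4.50), with Jchain at 5.52 (SE 0.75, adjusted p = 0.00726). Below Gadd45a (-3.97), the lower genes included Mid1 (-2.99), Lrmda (-2.09), Dio2 (-2.05), Erdr1 (-1.88), Tnc (-1.65), Hps1 (-1.63), Igf1 (-1.38) and Eln (-1.28). The other probe set of Hps1 was at -0.08, while those of Dio2, Tnc, Igf1 and Eln were lower too. The centred arrays gave 12 higher and 23 lower, a share of 34.3% higher against 24.0%. The count depended on single arrays, and only leaving out wild type SB replicate 1 kept it within 1.5 times. It was 161 without knockout VILI replicate 1, and 28 and 27 without knockout VILI replicates 2 and 3. It was 24 and 30 without wild type SB replicates 2 and 3, and 30, 33 and 29 without knockout SB replicates 1, 2 and 3. It was 22, 26 and 25 without wild type VILI replicates 1, 2 and 3. Of 24 named genes past the threshold, 19 stayed in each of the 12 fits. Col3a1 (-0.64) and Ddah1 (-1.07) lost the call in 10 each, Dio2 and Igkv15-103 in 8 each and Me1 (-0.63) in 3. Their highest adjusted p were 0.129, 0.137, 0.106, 0.109 and 0.0701, each without wild type VILI replicate 1. Of 27 lists, 14 were shifted and 0 held with an estimated correlation (smallest adjusted p = 0.183).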

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

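The count of shifted lists over splits of the arrays and the reading of the SB splits by parted pairs were chosen only after the results were seen, and the other tests in this part were set in advance.

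The VILI response of 8 lists differed between genotypes in the test of the difference itself (camera, preset correlation). It was more positive in knockout for acute cytokines and chemokines (adjusted p = 0.0317, 6 of 9 genes), interferon response genes (adjusted p = 0.00317, 15 of 17 genes), ciliated cell markers (adjusted p = 0.00472, 10 of 13 genes) and oxidative stress response genes (adjusted p = 0.00492, 14 of 19 genes). It was more negative in knockout for T and NK cell markers (adjusted p = 0.00142, 9 of 11 genes), macrophage and monocyte markers (adjusted p = 0.00317, 12 of 15 genes), endothelial markers (adjusted p = 0.00575, 15 of 24 genes) and type II epithelial markers (adjusted p = 0.00566, 13 of 15 genes). With an estimated correlation each had adjusted p = 0.748, and with fry 0.990. For the cytokines the adjusted p ranged from 0.00293 to 0.519 over the alternatives. Of the 100 drawn splits of the arrays, 59, the real one included, shifted at least as many lists as the 8 of the real one (highest other 17), so chance cannot be excluded for these shifts. For single genes the interaction called 0, the smallest count there can be, so all 100 splits reached it (highest other 7) and that comparison decides nothing.

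Probe sets without exactly 1 gene symbol stayed out of the comparisons of genes, and some of them passed the threshold when all 23082 kept probe sets were tested. Of 3424, 68 passed for VILI in wild type (59 higher, 9 lower), 55 for VILI in knockout (46 higher, 9 lower), 4 for knockout against wild type in SB (2 higher, 2 lower) and 4 after VILI (2 higher, 2 lower). They have no single gene name here.

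Other splits of the arrays show how many genes a grouping without the real labels calls. The 10 splits of 6 arrays are too few for a share under 0.05: only 1, the real one, reached 290 genes for VILI in wild type (highest other 2), and likewise 1 reached 491 for VILI in knockout (highest other 1), 1 reached 12 for genotype in SB (highest other 6) and 1 reached 11 for genotype after VILI (highest other 1). For genotype in SB, where the replicate numbers were taken as pairing, the 3 other splits that part all 3 pairs called 0 genes, and the 6 that part 1 pair called up to 6. The pairing was inferred from the same arrays, so this reading lends the SB calls no separate weight. For the averaged contrasts 1 of 100 splits, the real one, reached 1958 genes for VILI (highest other 7) and 50 genes for genotype (highest other 21). A random regrouping of the 12 arrays would thus rarely give counts this high. The genotype count was 22 without wild type VILI replicate 1, and splits were not drawn for that smaller set of arrays.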

How the results depend on the processing

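Leaving out the knockout arrays numbered 3 together and leaving out 3 arrays that stand apart (wild type SB replicate 2, knockout SB replicate 3 and knockout VILI replicate 3) were chosen after seeing the data, and the other alternatives were planned. No named gene past the threshold changed sign under an alternative. Of 8212 values of named genes not past it, 89 changed sign, among them Akt2 with VILI in wild type, at 0.20 with the mean of the probe sets against -0.16. Of the shifted lists, 5 recomputed tests turned direction without passing. For genotype after VILI these were cell cycle genes without knockout VILI replicate 3 (adjusted p = 0.350; range without 1 array 6.99e-08 to 0.350), without both knockout arrays numbered 3 (0.251) and without the 3 arrays that stand apart (0.270), and neutrophil markers without knockout VILI replicate 2 (0.436; range without 1 array 0.000783 to 0.582). For averaged genotype it was cell cycle genes without the 3 arrays (0.830). For named genes past the threshold, 5000 of 5803 recomputed values stayed past it and 803 did not. For named genes not past it, 7833 of 8212 were alike, 132 passed and 247 moved. For the lists, 4288 of 4644 kept their side, 233 lost the call, 118 gained one and 5 turned as above. The largest shift of the median of all genes by another scaling was 0.0783. Unless an alternative's construction shows it (fewer or more tests, fewer arrays), the cause of a change was not tested. Low signal limits the folds of genes near the lower end of the scale. Pseudocounts of 1 and 64 were not run because the values were already log2.

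With no brightness limit, 112 genes passed for VILI in wild type, 306 for VILI in knockout, 23 for the averaged genotype contrast, and 5 lists for the interaction. The lists for genotype were then 15 in SB (14 up, 1 down, 8 of them among the 12 with the limit, which were 7 up and 5 down), 10 after VILI (8 up, 2 down, against 8 and 6) and 11 averaged (10 up, 1 down, against 9 and 5), so most downward calls for genotype were lost. With all probe sets, 23 passed for genotype in SB, 23 for genotype after VILI, 3113 for averaged VILI and 90 for averaged genotype, and the correlation of the VILI responses was 0.674. With array weights the counts were 2204 and 872 for VILI in wild type and knockout, 44 for genotype after VILI, 3174 and 105 for the averaged contrasts, 9 lists for genotype after VILI and 4 for the interaction, and the correlation was 0.685. With only the 6 arrays of the 2 groups, 475 genes passed for VILI in wild type and 11 in knockout. With a fold of at least 2 the counts were 125 and 200 for VILI in wild type and knockout and 270 and 23 for averaged VILI and genotype. Quantile normalization left 9 lists for genotype after VILI. Without the neighbours of Gadd45a, 10, 9 and 34 genes passed for genotype in SB, after VILI and averaged.

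With both knockout arrays numbered 3 left out, 653 genes passed for VILI in wild type, 110 in knockout and 28 for averaged genotype, the lists were 6 for genotype in SB, 6 after VILI, 3 for the interaction and 9 for averaged genotype, and the correlation was 0.685. With the 3 arrays that stand apart left out, 125 genes passed for VILI in knockout, 19 for genotype after VILI and 22 for averaged genotype, the lists were 4 for genotype in SB, 6 after VILI, 2 for the interaction and 8 for averaged genotype, and the correlation was 0.642. Over genes past the threshold in either genotype it was 0.909. Camera with an estimated correlation left 1 list for VILI in wild type, 1 in knockout and 1 averaged, and 0 for genotype in SB, after VILI and averaged and 0 for the interaction. With fry the lists were 4 and 8 for VILI in wild type and knockout, 0 and 0 for genotype in SB and after VILI, 0 for the interaction and 1 for averaged genotype.

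Without single arrays the counts ranged from 19 to 487 for VILI in wild type, 69 to 713 in knockout, 9 to 18 for genotype in SB, 8 to 42 after VILI, 1128 to 2084 for averaged VILI and 22 to 161 for averaged genotype, and stayed at 0 for the interaction. The lists ranged from 10 to 14 and 10 to 16 for VILI in wild type and knockout, 6 to 14 and 6 to 15 for genotype in SB and after VILI, 3 to 9 for the interaction, and 10 to 15 and 12 to 16 for the averaged contrasts. The correlation ranged from 0.653 to 0.788.

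The replicate number as a block gave 442 genes for VILI in wild type, against 667 in knockout, 13 for genotype in SB and 10 after VILI, of which 275, 462, 11 and 8 had passed without it. Beside the genes named with that result, it changed no call for genotype in SB, lists included. After VILI it ended the calls of Igf1 (adjusted p = 0.0559), Mid1 and Smoc2 (0.0711 each) and added A2ml1 (0.0356) and Plin2 (0.0157). For comparisons other than genotype in SB the numbers were not taken as pairing: over all pairs of groups, deviations of arrays with the same number correlated at -0.163 to 0.526 (median 0.114), over 0.1 in 10 of 18 pairs, and 8 of 12 arrays correlated best with an array of their own number.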

Other observations

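The tests of plasma cell, B cell, T cell and clock genes, of the neighbours of Gadd45a, of called genes on other chromosomes and of other probe sets were chosen only after the results were seen, and so were the matrix genes named.

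With treatments averaged, the list of fibroblast and smooth muscle markers was shifted downward in knockout lungs: of 16, 3 were called lower (9 adjusted over the list alone) and 13 had a negative difference (median -0.44, camera adjusted p = 2.48e-05, and 0.262 with an estimated correlation; fry adjusted p = 0.0182). Marker lists of other cell types were shifted in the same contrast. B cell (median 1.21, adjusted p = 5.11e-06, and 0.477 with an estimated correlation), T and NK cell (0.58, adjusted p = 9.07e-05, and 0.417) and neutrophil markers (0.38, adjusted p = 0.000611, and 0.521; 0.0644 without knockout VILI replicate 2) went upward, type I epithelial (-0.22, adjusted p = 0.00408, and 0.521) and ciliated cell markers (-0.20, adjusted p = 0.00143, and 0.521) downward. Over the alternatives run with camera at the preset correlation, the highest adjusted p was 0.252 for B cells, 0.0670 for T and NK cells and 0.0644 for neutrophils. It was 0.239 for type I epithelium, 0.0600 for ciliated cells and 0.00399 for fibroblasts and smooth muscle. Some of the 38 lower genes encode proteins of the extracellular matrix, which were not tested as a set. Elastin, Eln, fell by 1.28 on the log2 scale (SE 0.14, adjusted p = 0.00189). Lower too were Loxl1 (-0.69, adjusted p = 0.0455), an enzyme that crosslinks elastic fibres, Ltbp1 (-0.58, adjusted p = 0.0238), which binds latent transforming growth factor beta, the collagen genes Col3a1 (-0.64, adjusted p = 0.0452) and Col6a3 (-0.75, adjusted p = 0.0432), Sparc (-0.49, adjusted p = 0.0306) and Tnc (-1.65, adjusted p = 0.00319). Igf1 (-1.38, adjusted p = 0.00155) and Igfbp2 (-0.66, adjusted p = 0.0241), a growth factor and a binding protein of it, were also lower. Col1a1 (-0.80, adjusted p = 0.147) did not pass, and the matrix gene Fbln2 was higher (1.97). In the 12 fits without 1 array, Eln, Tnc, Igf1 and Fbln2 stayed past the threshold, while Col6a3 lost its call in 11, Col3a1, Loxl1 and Sparc in 10 each, Ltbp1 in 9 and Igfbp2 in 6. The highest adjusted p was 0.139 for Loxl1, 0.135 for Col6a3, 0.129 for Col3a1 and 0.109 for Sparc without wild type VILI replicate 1, and 0.0734 for Ltbp1 and 0.0731 for Igfbp2 without wild type SB replicates 3 and 2.

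The first pattern was the excess of immunoglobulin transcripts in knockout lungs, and a sequence variant of the immunoglobulin loci between the strains is argued against as its whole cause: 8 plasma cell genes outside the loci, Jchain left out, differed by a mean of 0.91 (SE 0.37, exact permutation p = 0.005, two-sided, the smallest that 400 assignments within treatments can give). That mean rested mostly on Mzb1 (2.92), Pou2af1 (2.01), which is also in the B cell list, and Irf4 (1.43). The others of the 8 lay between -0.22 (Sdc1) and 0.40 (Prdm1). Jchain (5.52) was the only plasma cell gene past the threshold, and 10 B cell markers without Jchain and Ighm, with a mean of 1.23, did not pass (exact permutation p = 0.13). More lymphoid tissue of every kind in the knockout samples remains a candidate for part of the excess. The 7 T cell genes were higher by a mean of 1.16 (SE 0.40, exact permutation p = 0.005), and 11 immunoglobulin genes by 3.60 (SE 0.64). Knockout SB replicates 1 and 2 and knockout VILI replicate 2 had B cell means of 7.44, 6.94 and 7.12 (wild type up to 7.30). Their immunoglobulin means were 8.64, 8.03 and 9.01 (wild type up to 6.69). T cell means were 6.37 or above on each knockout array and 6.34 or below on each wild type array. Without the knockout arrays numbered 3 the differences were 0.41 for the 8 plasma cell genes, 2.88 for 11 immunoglobulin genes (3.60 with them), 0.63 for 12 B cell markers (1.54 with them) and 0.72 for T cell genes. The genotype itself, which the design names, stays open as an untested hypothesis, as do animal housing and strain.

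The second pattern was the set of genes that differed by genotype with treatments averaged. Of the called genes, 39 lie on other chromosomes, outside linked sequence of the targeted strain around Gadd45a. They outnumber the 21 genes of the highest other split of the arrays. Whether linked variants changed them indirectly was not tested. Near Gadd45a, 4 of 393 genes were called against 39 of 10590 elsewhere with immunoglobulin genes left out (Fisher's exact p = 0.0667). With them it was 9 of 400 against 40 of 10595 (Fisher's exact p = 5.76e-05), and 5 of the 9 are kappa genes. The near genes were 400 of the 586 measured genes on that chromosome. Distant genes can therefore dilute an excess close to Gadd45a, and linked sequence stays open for the near genes. Probe sequence variants that affect single probe sets are argued against as the main cause for the 24 of 50 called genes with another kept probe set. By sign alone, 37 of the 39 other probe sets went the same way. A probe set counted as differing the same way when its unadjusted limma p was also under 0.05. Most of a gene's other probe sets did so in 18 of the 24 genes (75%, exact 95% interval 53.3 to 90.2). All of them did in 17 (48.9 to 87.4). Both of Anxa4 went the other way (0.45 and 0.31), and that of Hps1 was at -0.08, against -1.63 for the one used. Those of Synpo2 (-0.46, -0.08 and -0.33), Vps37a (-0.17 and -0.06) and Ltbp1 (-0.41) were lower without reaching that p. For Cdh13 they were at -0.63 and -0.11, and only the first reached it. For these genes, Anxa4, Hps1 and the 26 called genes without another kept probe set, probe sequence variants stay open. A different strain background stays open, because strain is not given; Nnt, higher in knockout by 1.43, is known to carry a deletion in C57BL/6J mice.

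The third pattern was the fall of clock genes with VILI, weighed on the clock genes of the list fixed in advance. A shift in the time of day of collection is a candidate explanation in wild type, where 4 genes that peak with Bmal1 had a mean change of 1.08 (95% interval 0.44 to 1.72) and the 10 others of -1.06 (95% interval -1.45 to -0.67). In knockout the means were 0.15 (95% interval -0.49 to 0.79) and -0.45 (95% interval -0.84 to -0.06), so it stays open there, and the interaction called 0 of these genes. The mean of the 4 in wild type rested mostly on Bmal1 itself (2.28, adjusted p = 0.0523) and Npas2 (1.35, adjusted p = 0.200). Cry1 (0.47, adjusted p = 0.188) and Clock (0.23, adjusted p = 0.307) changed less, and none of the 4 passed. In wild type the 10 clock genes fell more than resident cell markers, which changed by -0.31, a gap of 0.74 (95% interval 0.42 to 1.07). In knockout the gap was 0.15 (95% interval -0.17 to 0.47). The 10 genes include Dbp, Per3 and Nr1d2, whose falls were seen first. The markers were a single mean over several cell types, which cannot show loss of a single type. A lower share of resident lung cells after VILI therefore stays open in both genotypes. Collection times are not given, so time of day and an effect of injury on the clock were not separated.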
